A study of Homo sapiens with 18 samples.

How the data were processed

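The series holds 18 CUT&Tag libraries of MCF-7 cells, of which the 6 IgG control libraries (2 per treatment) were not analysed here. The 12 libraries analysed cover ER and H3K27ac in cells left for 45 min with vehicle, with E2 at 1 nM or with FULV at 100 nM, with 2 biological replicates per condition, per the labels' protocols. Each library was made from 100000 cells with 14 PCR cycles and sequenced in paired reads of 38 bp, per the labels' protocols.

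The processing notes of the submitters name Trimmomatic, Bowtie2, Picard, SAMtools and MACS3 and the genome build hg38. Tool versions, the counting program and the way in which the replicates were joined into consensus lists are not given in the sources used here. The authors deposited whole-number counts per region without normalization, as 3 matrices per the file headers: ER in 43939 merged ER regions, H3K27ac in 37460 merged H3K27ac regions, and H3K27ac in windows of about 1 kb on the centres of the ER regions. Every window had the identifier of an ER region and the same centre within 1 bp. The authors also deposited 1 consensus list of regions per treatment and target, with a peak score, a fold enrichment as a ratio and -log10 p and q values. The score equalled 10 times the -log10 q in 100% of the deposited rows within rounding, and these values describe regions of 1 list only. The control behind the deposited fold enrichment is not given in the sources used here. How counts were made limits what they show: PCR reads have no molecular identifiers, and the regions were called on the same libraries that were then counted.

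Samples were grouped by target and treatment from their titles, and 0 count columns matched no sample. Total counts in regions ran from 222569 to 3879015 in the ER libraries and from 2227599 to 3698285 in the H3K27ac libraries, and the total of mapped reads was not used here. Replicates were compared before averaging: the chi-square per degree of freedom between replicates was 1.17 to 2.26 over regions with at least 20 counts in the pair, so no pair agreed within sampling noise and none was merged. The Pearson correlation of log2 CPM between replicates was 0.721 for ER in DMSO and at least 0.949 for the other pairs. Intervals on overlaps of the region lists are Wilson 95% intervals, those on shares of called regions are exact (Clopper-Pearson) 95% intervals, and both cover counting error only.

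Tests used edgeR 4.0.16 in R 4.3.3 on the deposited counts, with filterByExpr, TMM factors, the quasi-likelihood F test and Benjamini-Hochberg adjustment, at a threshold of 0.05. All 6 libraries of a matrix entered 1 fit with treatment as the only term, which leaves 3 residual degrees of freedom, because groups of 2 give too few alone. Filtering kept 39000 ER regions, 35420 H3K27ac regions and 29811 windows. TMM factors were 0.703 to 1.34 for ER and 0.949 to 1.09 for H3K27ac, and the windows took library sizes and factors from the H3K27ac regions, so that a change common to ER sites stays visible. Common biological coefficients of variation were 0.110, 0.0848 and 0.0901. TMM sets the bulk of regions to no change, so a gain or loss of ER at all regions alike cannot be seen. Fitted log2 changes carry a prior count of 0.125, and log2 CPM levels one of 2. The SE printed with a log2 change is its absolute value divided by the square root of the F statistic. It is not a direct estimate and can lie below the counting error where counts are few. ER-gained sites are those that rose in the ER libraries, so that the choice of sites and the H3K27ac test use separate libraries, and they were tested with fry (limma 3.58.1), which asks whether the members move one way on balance. Its p values were adjusted over the 27 pairs of site group and contrast, a step added after the results were seen. Gene lists were tested with camera, with an estimated correlation between regions and with the preset one, adjusted over the 8 lists of a contrast. Overlaps used bedtools 2.31.1 with at least 1 bp, and other steps Python 3.11.15.

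Regions took the name of a protein-coding gene from a RefSeq table of the assembly GRCh38.p14, whose coordinates share the build of the files. The table used gives gene starts and ends without strand and no exons. The plan had been to name regions by the nearest transcription start site within 100 kb. In its place a region took the gene whose body lay nearest to its midpoint within 100 kb, at 0 inside, with ties decided by the nearer gene end. Nearness to a promoter was replaced by a distance of at most 1 kb to either gene end. Positions in exons, introns and untranslated regions and the planned motif analysis need a genome or a fuller annotation and were not run. Of 20056 protein-coding genes listed, 19286 were used, without read-through and uncharacterised entries, and 38567 ER and 35735 H3K27ac regions had a gene. Many regions lie far from the gene they are named for, and the name does not say that the gene is regulated there.

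The rule for named regions took, per contrast of the ER and H3K27ac regions, the 10 that rose and the 10 that fell with the smallest p, among called regions with a mean above the median and no overlap between the replicates of both groups, 1 per gene. It added the region with the highest mean count of each of GREB1, TFF1, PGR, MYC, XBP1, NRIP1, RARA, CCND1, ESR1 and GATA3. The text gives a part of these and members of 8 gene lists: estrogen-induced, luminal identity, ER coregulator and chromatin enzyme, immediate early and AP-1, cell cycle, housekeeping, basal and mesenchymal, and other lineages. The lists, the naming rule, the main fits and the other settings to be tried were fixed before the data were examined.

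The alternatives were DESeq2 1.42.0 with its size factors, library totals without TMM, unscaled counts, TMM on the ER windows, no count filter, a replicate number block, leaving out each library in turn, a prior count of 5, a gene distance of 10 kb, an overlap of 50%, and the regions above the median score. TMM on regions within 1 kb of a gene end and TMM on the regions in all 3 ER lists were added after seeing the data. For E2 and FULV against the same DMSO libraries, 20 simulations of unchanged groups gave the values that shared controls produce alone.

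The tests were tested on simulated data with the means and sizes of the real libraries and 200 changed regions per contrast. A further set of regions was given a smaller shift under E2. For ER with E2 against DMSO, over 31531 regions, 6% of 2-fold and 38% of 4-fold changes were recovered, and for FULV 11% and 46%. For H3K27ac regions (34539) the shares were 55% and 93% with E2 and 53% and 85% with FULV, and for H3K27ac at ER windows (28702) 48% and 78%, and 46% and 87%. Unchanged regions made up 3 of 47 calls for ER with E2 and 1 of 58 with FULV. They were 14 of 167 and 7 of 145 for H3K27ac regions, and 10 of 144 and 10 of 143 at ER windows. The real fits called more regions than were changed here, so these shares may not carry over to them.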

Results

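MCF-7 cells, an estrogen receptor positive human breast cancer line, were kept without hormone for 4 to 5 days and then given DMSO, 1 nM estradiol (E2, the natural ligand of the receptor) or 100 nM fulvestrant (FULV, a pure antagonist that also leads to loss of the receptor protein) for 45 min. CUT&Tag, in which an antibody guides a transposase to cut the DNA near its target, was used to map the estrogen receptor (ER) and H3K27ac, the histone acetylation found at active promoters and enhancers. Counts were analysed for 12 libraries, with 2 biological replicates for each of the 6 pairs of target and treatment. The design asks where ER lies on chromatin with an agonist and with an antagonist, and whether acetylation at the same places follows ER. Counts in the 43939 ER regions came to 222569 and 428850 in the DMSO libraries, 2631967 and 2024069 under E2 and 3879015 and 3111733 under FULV. The treated means were 7.15 and 10.7 times the DMSO mean. The median ER region held 2 and 5 counts in the DMSO libraries and 30 and 34 in the FULV libraries. In the 37460 H3K27ac regions the totals were 2227599 and 2409030 with DMSO, 3698285 and 3011593 with E2 and 3100380 and 3381498 with FULV. These totals are counts inside called regions and do not give the sequencing depth, so a higher ER total cannot be told from deeper sequencing here. Levels below are TMM-scaled CPM (counts scaled to a library of 1e6), given as mean ± SD with n = 2, and changes are log2 ratios relative to the bulk of regions. Unless another test is named, an adjusted p comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR QL), and "rose", "fell" and "called" refer to an adjusted p below 0.05.

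**Figure D1:**
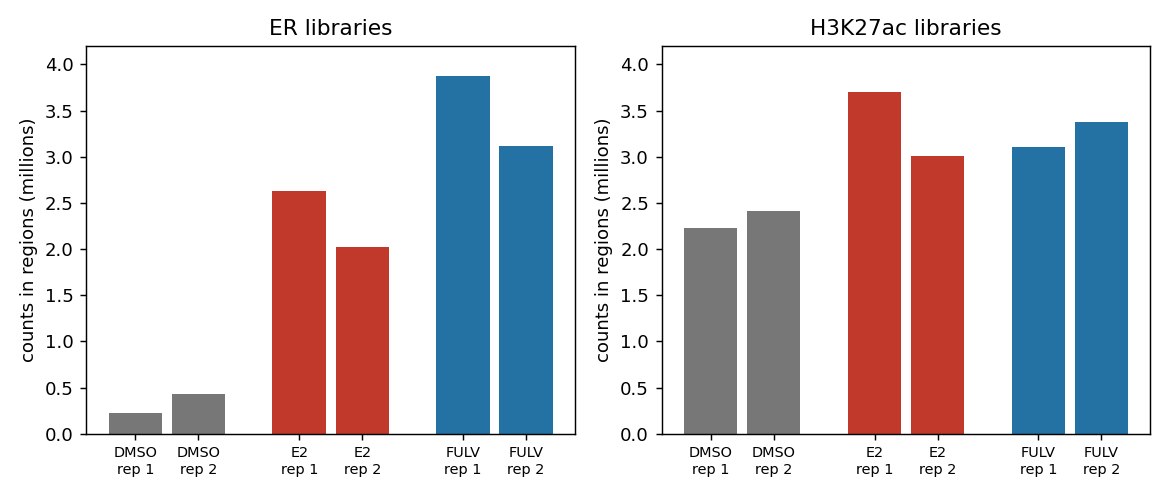
Counts inside regions per library (bars, axis from 0), for ER in the 43939 ER regions and for H3K27ac in the 37460 H3K27ac regions. The ER DMSO libraries hold 222569 and 428850 counts, below each of the treated ER libraries, of which the lowest holds 2024069.

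The authors' consensus lists held 2489 ER regions for DMSO, 22863 for E2 and 40993 for FULV, with median widths of 555, 604 and 627 bp and covered lengths of 1.44, 14.7 and 27.5 Mb. ER regions of the E2 list were largely found again with FULV. Of them, 87.0% (95% Wilson interval 86.6 to 87.4) overlapped a FULV region by at least 1 bp, and 48.2% of the FULV regions overlapped an E2 region. The DMSO regions lay inside both treated lists, at 90.8% for E2 and 95.5% for FULV. After merging, 21138 of the 43939 ER regions (48.1%) were listed for FULV alone, 17395 (39.6%) for E2 and FULV, 2963 (6.74%) for E2 alone and 2216 (5.04%) for all 3 treatments. H3K27ac lists were closer in length, with 28140, 29049 and 31119 regions for DMSO, E2 and FULV, and 19779 of the 37460 merged regions (52.8%) were in all 3 lists. ER regions overlapped the H3K27ac list of the same treatment at 70.6% for DMSO, 46.5% for E2 and 42.7% for FULV. Regions within 1 kb of an end of a protein-coding gene made up 8.76, 12.3 and 14.1% of the ER lists and 31.8, 33.6 and 32.3% of the H3K27ac lists. There was 1 list per treatment and target, so these shares have no replicate error, and the length of a list moves with the counts behind it.

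With E2 against DMSO, ER rose at the classical estrogen target genes. At the enhancer inside GREB1, an estrogen-induced growth regulator (chromosome 2, 11539200 to 11540687, 57.1 kb from the nearer gene end), ER went from 462 ± 222 to 2023 ± 43.2 CPM, a log2 change of 2.18 (SE 0.273, edgeR QL adjusted p = 6.19e-07). The region 0.167 kb from TFF1, which encodes a secreted trefoil peptide (chromosome 21, 42366226 to 42367178), went from 397 ± 114 to 1923 ± 57.4 CPM (log2 change 2.31). The region 57.9 kb from the proto-oncogene MYC (chromosome 8, 127799884 to 127801773) went from 335 ± 107 to 2544 ± 50.2 CPM (2.97). ER also rose at the panel regions of PGR, the progesterone receptor gene (2.61), NRIP1, a nuclear receptor corepressor gene (2.71), XBP1, a transcription factor of the unfolded protein response (1.99), CCND1, the cyclin D1 gene (1.65), GATA3, a luminal transcription factor gene (1.56), RARA, a retinoic acid receptor gene (1.23), and ESR1, which encodes ER itself (0.66). The regions that rose with the smallest p included one inside PNPLA7 (chromosome 9, 137513719 to 137514680), with 7.91 ± 3.81 CPM in DMSO and 813 ± 49.5 in E2 (log2 change 6.84, SE 0.355, edgeR QL adjusted p = 7.25e-12), one inside TH, the tyrosine hydroxylase gene (chromosome 11, 2168663 to 2169906), with 54.5 ± 27.9 and 1938 ± 4.54 CPM (5.30). Another lay 24 kb from JARID2, a gene of the Polycomb complex (5.79). The DMSO level at PNPLA7 rests on 3 counts in each library, so the SE there understates the counting error. Among the regions that fell with the smallest p, 4 lay within a stretch of chromosome 8 near PLEC (-3.04), SCRIB (-3.01), EPPK1 (-3.82) and PUF60 (-2.82). Others lay near gene ends of RSL24D1 (-2.63) and INTS2 (-2.48).

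Of the 39000 ER regions tested, 8190 rose and 4523 fell with E2 against DMSO, 7629 and 4059 of them by at least 2-fold. Scaling by library totals without TMM gave 4070 and 12432, TMM set on the regions in all 3 ER lists 4042 and 12009, and unscaled counts 24082 and 66. These scalings moved the median change of all regions by -0.89, -0.88 and 1.90 relative to the TMM fit. At the panel regions, ESR1 was at -0.24 and RARA lost its call with library totals, and of the 10 regions named for the smallest p among those that fell, unscaled counts kept 3. Without DMSO replicate 2 the calls came to 6760, of which 5204 rose and 1556 fell. The count that fell was 2913 without E2 replicate 1 and 2825 without E2 replicate 2. The call at ESR1 was lost without E2 replicate 1 (log2 change 0.61) and without E2 replicate 2 (0.74).

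Among the gene lists, ER rose with E2 at 144 of the 238 regions of estrogen-induced genes and fell at 3 (152 and 3 adjusted over the list alone), with a rise near 28 of the 30 genes. Examples were KRT13, a keratin gene (79.9 ± 22 to 987 ± 39.2 CPM, log2 change 3.70), RET, a receptor tyrosine kinase gene (3.77), and ELOVL2, a fatty acid elongase gene (2.90). The list stood out with a preset correlation of regions (camera, adjusted p = 4.09e-21) but not with an estimated one (adjusted p = 0.164 with an estimated correlation). Luminal identity genes had 52 regions that rose and 18 that fell of 148 (57 and 20 adjusted over the list alone), among them a rise at PBX1 (3.47) and ELF3 (2.69) and a fall near ERBB3 (-1.77). Immediate early and AP-1 genes had 38 that rose and 8 that fell of 99 (41 and 13 adjusted over the list alone), such as a region 24 kb from FOS (107 ± 28.5 to 967 ± 31.7 CPM, 3.24). ER coregulator and chromatin enzyme genes had 13 that rose and 24 that fell of 85 (13 and 25 adjusted over the list alone), with NCOR2 among the former (4.74) and NCOA3 among the latter (344 ± 26.0 to 123 ± 8.43 CPM, -1.49). These rises lay near 4 genes and the falls near 7, of 12 with regions. With an estimated correlation the camera adjusted p was 0.164 for the luminal and immediate early lists and 0.456 for the coregulator list, while the preset correlation gave 0.0180, 0.00366 and 0.00965. The counts were 4 and 2 of 17 for cell cycle genes, 5 and 5 of 23 for housekeeping genes, 7 and 1 of 42 for basal and mesenchymal genes (3 and 0 adjusted over the list alone) and 5 and 2 of 23 for genes of other lineages, none of which camera called. The other-lineage list had a median of -0.55, a mean of 0.14 and a test direction upward, the cell cycle list a median of 0.15 and a test direction downward, and the housekeeping list a mean of 0.26 against a median of -0.07. With library totals the luminal list had 22 regions that rose and 49 that fell and the immediate early list 24 and 27. The estrogen-induced list kept its direction at 90 and 9. Coregulator genes had 7 and 41 with library totals and 40 and 0 without scaling.

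**Figure D2:**
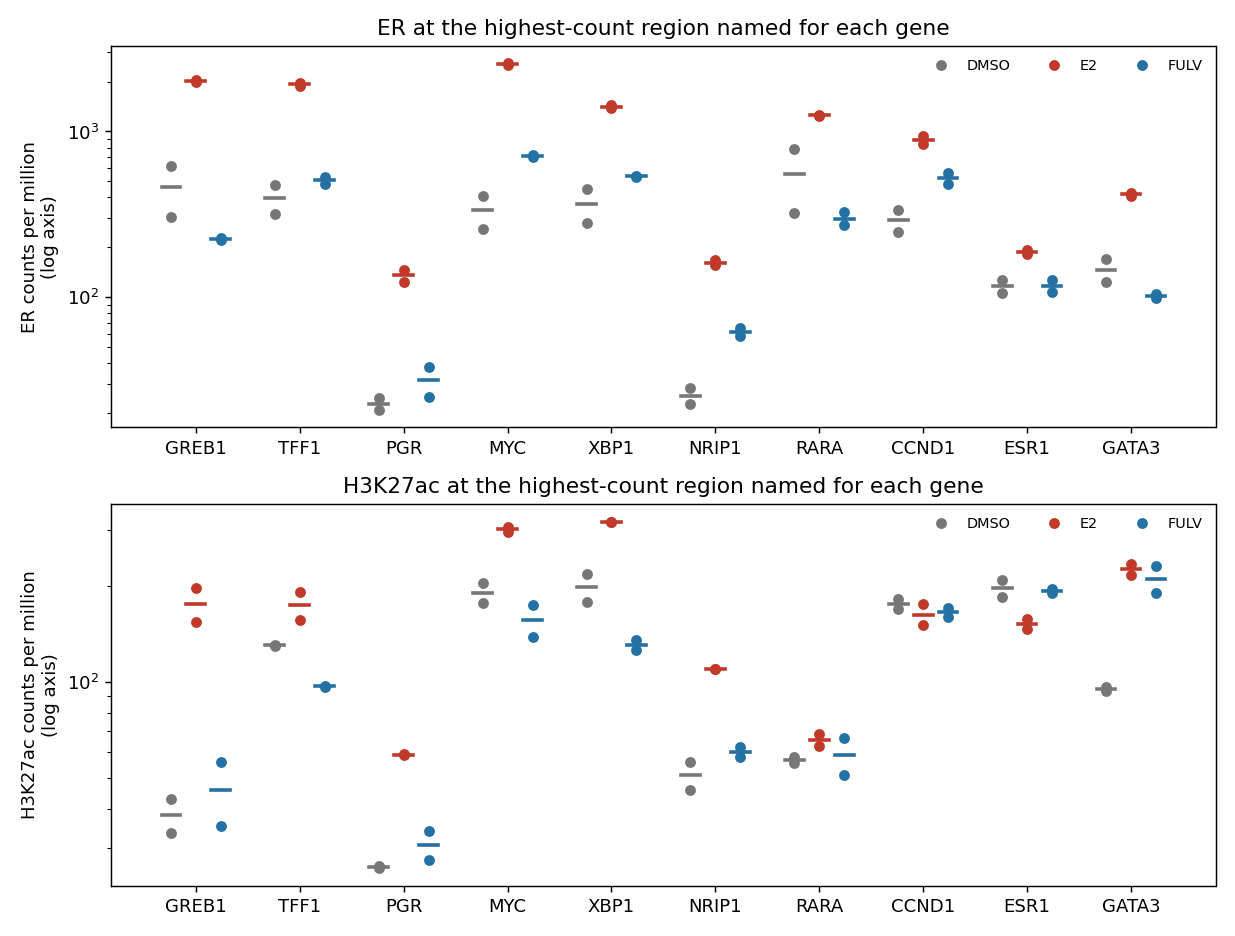
Levels at the panel regions of 10 genes, for ER (upper panel) and H3K27ac (lower panel), in TMM-scaled CPM on a log axis, with a point per library and a bar at the mean of each treatment. At the GREB1 ER region the E2 mean is 2023 CPM, against 462 in DMSO and 225 in FULV.

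For FULV against DMSO, ER regions that rose with the smallest p are given first, and the panel regions after them. The former were picked among all regions for their p and the panel was fixed by gene, so no comparison of them is drawn. ER was at 24.5 ± 4.69 CPM in DMSO and 195 ± 6.34 in FULV at a region 11.4 kb from ZKSCAN1, a zinc finger gene (chromosome 7, 100003625 to 100004747, log2 change 2.93, SE 0.256, edgeR QL adjusted p = 8.77e-08), where E2 gave 80.3 ± 1.14 CPM. It also rose inside WFS1, an endoplasmic reticulum membrane protein gene (3.36), inside ZMIZ1, a transcriptional coactivator gene (3.03), and 0.497 kb from ZFP36, which encodes an RNA-decay factor (chromosome 19, 39409439 to 39410369, 33.3 ± 2.11 to 296 ± 94.3 CPM, 3.13). In the panel, ER rose at MYC (335 ± 107 to 712 ± 12.5 CPM, log2 change 1.13), NRIP1 (1.33) and CCND1 (0.88) and fell at GREB1 (462 ± 222 to 225 ± 4.01 CPM, -0.98, edgeR QL adjusted p = 0.0117) and RARA (-0.84, adjusted p = 0.0344). TFF1 (0.39), PGR (0.51), XBP1 (0.60), GATA3 (-0.48) and ESR1 (-0.02) did not pass the test. Regions that fell included ones near PLEC (-4.01), RSL24D1 (-3.30), SCRIB (-3.10) and PERM1 (-2.89).

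In all, 4702 ER regions rose and 3066 fell with FULV against DMSO, 4085 and 2619 of them by at least 2-fold. Library totals gave 3224 and 4601, TMM on the regions in all 3 ER lists 2559 and 5227, and unscaled counts 38122 and 10. The median shifts were -0.28, -0.40 and 3.10. Without scaling, GREB1 (2.29) and RARA (2.48) were called higher under FULV and of the 10 regions named for the smallest p among those that fell 2 kept their call. Those near PLEC (-0.90), RSL24D1 (-0.18) and SCRIB (0) lost it, and those near PERM1, ATRNL1, INTS2, ARL4D and TUT1 changed sign. Without DMSO replicate 2 the calls came to 3070, of which 1982 rose and 1088 fell, and NRIP1 was not called (log2 change 1.16). RARA was not called without DMSO replicate 1 (-0.10), E2 replicate 1 (-0.86), E2 replicate 2 (-0.84) or FULV replicate 2 (-0.71). GREB1 was not called without E2 replicate 2 (-0.98) or FULV replicate 1 (-0.95), and CCND1 was not called without E2 replicate 2 (0.89) or FULV replicate 1 (0.77).

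Near estrogen-induced genes, 32 of 238 ER regions rose and 23 fell with FULV (33 and 28 adjusted over the list alone), so that the list held both directions. At RET, 50.5 kb from the gene, ER went from 35.2 ± 20.2 to 205 ± 23.5 CPM (log2 change 2.73). At MYB, a proto-oncogene, it went from 8.73 ± 7.35 to 79.2 ± 25.2 CPM (2.92). Inside PGR a distal region fell from 28.1 ± 0.311 to 4.82 ± 1.29 CPM (-2.54). The DMSO levels at the MYB and PGR regions rest on few counts, and their SDs do not cover counting error. At this PGR region the unscaled counts were not lower with FULV, so its fall depends on the scaling. SIAH2, a ubiquitin ligase gene (-0.83), and CTSD, the cathepsin D gene (-0.77), had regions that fell as well. Luminal identity genes had 34 that rose and 7 that fell of 148 (40 and 13 adjusted over the list alone), including rises at TFAP2C (2.05), CDH1, the E-cadherin gene (2.30), and FOXA1, a pioneer factor gene (1.40). The other lists had 8 and 16 of 85 (coregulators, 9 and 17 adjusted over the list alone), 15 and 6 of 99 (immediate early, the same counts over the list alone), 1 and 2 of 17 (cell cycle), 2 and 4 of 23 (housekeeping, 5 and 5 adjusted over the list alone), 1 and 1 of 42 (basal) and 4 and 1 of 23 (other lineages). The coregulator rises lay near 3 genes and the falls near 3, of 12 with regions. No list passed camera with either correlation, the lowest adjusted p being 0.506 with an estimated correlation. The housekeeping list had a mean of 0.07 against a median of -0.06. With library totals the estrogen-induced counts were 20 and 34 and the luminal counts 24 and 24. Without scaling 225 and 148 regions of these lists rose and 0 fell in either.

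Compared directly, ER was lower with FULV than with E2 at the estrogen target genes. At the GREB1 panel region the log2 change was -3.17 (SE 0.265, edgeR QL adjusted p = 5.67e-10), and it was -1.92 at TFF1, -2.09 at PGR, -1.84 at MYC, -2.07 at RARA, -2.03 at GATA3, -1.39 at XBP1, -1.38 at NRIP1, -0.77 at CCND1 and -0.68 at ESR1. Inside GREB1 a further region (chromosome 2, 11524172 to 11524949) had 246 ± 8.71 CPM with E2 and 10.9 ± 2.50 with FULV (-4.47). Regions inside LPP, a focal adhesion gene (-4.32), and 53.7 kb from RAMP3, a receptor activity-modifying protein gene (-3.95), had similar differences. ER was higher with FULV at other places, such as a region 13.0 kb from IMPA1, an inositol monophosphatase gene (32.1 ± 1.95 to 140 ± 6.48 CPM, 2.12), one inside MB, the myoglobin gene (38.8 ± 2.47 to 162 ± 15.1 CPM, 2.05), and one 26.7 kb from EFEMP1, an extracellular matrix gene (3.42).

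ER was higher under FULV at 6724 regions and lower at 9681, of which 4780 and 7229 differed by at least 2-fold. DESeq2 called 2093 higher and 6878 lower, library totals 17875 and 5649, TMM on the regions in all 3 ER lists 14840 and 6328, and unscaled counts 22946 and 1901. The last 3 had median shifts of 0.62, 0.49 and 1.20. Without scaling the calls at TFF1, PGR, MYC, XBP1 and NRIP1 were lost and CCND1 (0.44) and ESR1 (0.52) changed sign. With library totals CCND1 and ESR1 were not called. Without E2 replicate 1 the calls came to 10002, 3123 higher and 6879 lower, and CCND1 (-0.66) and ESR1 (-0.62) were not called. Without E2 replicate 2 the calls were 3274 higher and 7770 lower. CCND1 was not called without E2 replicate 2 (-0.87) or FULV replicate 2 (-0.65) either. Of the 238 regions of estrogen-induced genes 195 were lower under FULV and 1, near AREG, was higher (201 and 1 adjusted over the list alone). The list was called with an estimated correlation (camera adjusted p = 0.0290). It stayed lower with library totals, at 149 against 12, and without scaling, at 57 against 19. The immediate early list had 43 lower and 11 higher of 99 (44 and 11 adjusted over the list alone), with a camera adjusted p of 0.00103 with the preset and 0.0571 with an estimated correlation. The luminal list had 48 lower and 12 higher of 148. With library totals these became 33 lower and 35 higher and 18 lower and 55 higher, respectively. The remaining lists had 17 lower and 20 higher of 85 (coregulators), 7 and 2 of 17 (cell cycle), 5 and 2 of 23 (housekeeping, 4 and 0 adjusted over the list alone), 11 and 4 of 42 (basal) and 6 and 4 of 23 (other lineages, median 0.20, mean -0.05, test direction downward), without a camera call. With library totals these lists had, in the same order, 6 lower and 46 higher, 5 and 7, 2 and 8, 6 and 10, and 6 and 13.

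The ER changes under the 2 treatments were shared at many regions. Of the 4702 regions that rose with FULV, 3295 (70.1%) also rose with E2, among them MYC, NRIP1 and CCND1, where lists of these sizes would share 987 if independent, and 2050 fell under both against 356. Opposite calls were made at 112 regions, GREB1 and RARA among them. Both contrasts use the same DMSO libraries. The Pearson correlation of the changes across 39000 regions was 0.702, where 20 simulations of unchanged groups against these controls gave a mean of 0.907. The simulations gave no shared call, but without simulated changes hardly any call can arise. They therefore do not show how many shared calls come from the shared controls. The covariance was 1.40 against 0.664 simulated, a difference of 0.739. With 1 DMSO library for each contrast, both ways, the correlation was 0.359 and 0.287 and the covariance 0.608 and 0.546, from log2 CPM levels. Since each control then has 1 library, part of the excess may come from the shared controls. Regions are not independent replicates, so these correlations carry no p.

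With E2 against DMSO, H3K27ac rose at regions of estrogen targets, of some AP-1 genes and near the ends of many other genes. Of the lists, neither the estrogen-induced nor the immediate early and AP-1 genes passed camera with an estimated correlation. At an end of GREB1 (chromosome 2, 11482122 to 11483783, 0.064 kb from it) H3K27ac went from 38.3 ± 6.64 to 176 ± 31.0 CPM. The log2 change was 2.21 (SE 0.181, edgeR QL adjusted p = 3.79e-09). Without strand, a gene end may be the start or the stop of the gene. At FOSL2, which encodes an AP-1 subunit (chromosome 2, 28392205 to 28393604), it went from 46.5 ± 0.440 to 233 ± 4.66 CPM (2.32). At TH it went from 20 ± 1.87 to 98.2 ± 7.41 CPM (2.29) and 29.7 kb from DICER1, the gene of the small RNA processing enzyme, from 31.5 ± 1.85 to 131 ± 8.23 CPM (2.06). H3K27ac rose at the panel regions of GATA3 (1.25), PGR (1.17), NRIP1 (1.11), XBP1 (0.68), MYC (0.66) and TFF1 (0.41) and fell at that of ESR1 (-0.37). It did not pass the test at RARA (0.20) and CCND1 (-0.11). Regions that fell included ones 41.6 kb from FBXW7, a ubiquitin ligase gene (98.2 ± 1.85 to 52.4 ± 5.67 CPM, -0.91), 78.9 kb from BCAS1 (-0.80), 93.3 kb from PTGS2, the COX-2 gene (-1.58), and inside PDE4D, a phosphodiesterase gene (-1.32). Of the 10 regions named for the smallest p among those that fell, unscaled counts kept 5, and the one near BCAS1 lost its call (-0.44).

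Of 35420 regions 5748 rose and 1744 fell. DESeq2 called 3583 and 210, library totals gave 4597 and 4588, unscaled counts 8719 and 90 and TMM set on regions near gene ends 3779 and 8021. The last 3 had median shifts of -0.16, 0.37 and -0.29. The call at TFF1 was lost with library totals and with TMM near gene ends. It was also lost without DMSO replicate 1 (0.445), DMSO replicate 2 (0.43) or E2 replicate 2 (0.29). The call at ESR1 was 0.01 and not called without scaling and was lost without DMSO replicate 1 (-0.26), DMSO replicate 2 (-0.43), E2 replicate 1 (-0.42) or E2 replicate 2 (-0.29). The calls came to 3802 without DMSO replicate 2 and 3962 without E2 replicate 1. The count that fell was 728 and 298 without DMSO replicates 1 and 2, 329 and 603 without E2 replicates 1 and 2, and 2484 and 2738 without FULV replicates 1 and 2. The count that rose was 3504 without DMSO replicate 2 and 3633 without E2 replicate 1. Near estrogen-induced genes 70 of 153 regions rose and 1 fell, near MYC (74 and 3 adjusted over the list alone). IGFBP4, an IGF-binding protein gene (27.9 ± 4.42 to 80.3 ± 5.64 CPM, 1.53), and CELSR2 (1.74) were among the former. Camera gave an adjusted p of 0.0546 with an estimated correlation and 4.68e-12 with the preset one. Immediate early and AP-1 genes had 23 of 69 that rose, near 12 of the 15 genes, and 1 that fell, near IER2 (23 and 2 adjusted over the list alone). Their list had a camera adjusted p = 0.330 with an estimated correlation and 6e-05 with the preset one. Luminal identity genes had 21 and 12 of 187 (19 and 11 adjusted over the list alone), coregulators 14 and 12 of 149 (14 and 4 adjusted over the list alone), cell cycle genes 6 and 2 of 25 (8 and 2 adjusted over the list alone), housekeeping genes 7 and 1 of 34, basal genes 0 and 1 of 19, and other lineages 2 and 0 of 8, near TNNT2 and INS (3 and 0 adjusted over the list alone). With TMM set near gene ends the luminal list had 16 that rose and 61 that fell and the estrogen-induced list 50 and 14. The immediate early list then had 16 and 8 and the coregulator list 10 and 53. With library totals the coregulator list had 12 and 34.

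With FULV against DMSO, H3K27ac rose at regions that E2 also raised and not at most estrogen panel regions. At NFKBIZ, a nuclear regulator of NF-kB (chromosome 3, 101848842 to 101850271), it went from 18.8 ± 1.73 to 105 ± 18.8 CPM (log2 change 2.48, SE 0.178, edgeR QL adjusted p = 3.11e-09), where E2 gave 86.3 ± 5.69. It rose at MYL12B, a myosin light chain gene (143 ± 3 to 421 ± 14.7 CPM, 1.56), UBE2J1, a ubiquitin-conjugating enzyme gene (2.15), RAB2A, a small GTPase gene (2.21), and LATS2, a Hippo pathway kinase gene (2.61), and at the panel region of GATA3 (95.2 ± 1.91 to 210 ± 28.4 CPM, 1.14). Some regions that E2 raised fell with FULV, such as one inside SHANK2, a scaffold protein gene (chromosome 11, 70804600 to 70806687, 108 ± 23.6 CPM in DMSO, 207 ± 8.70 in E2 and 39.0 ± 2.03 in FULV, -1.46), one 39.3 kb from CYP2A7 (-1.80) and one 13.2 kb from XBP1 (98.0 ± 4.68 to 51.6 ± 0.525 CPM, -0.92). Over all 652 regions that fell with FULV the median change with E2 was -0.40, and 147 of them also fell with E2 while 93 H3K27ac regions were called in opposite directions. The panel regions of XBP1 (-0.60) and TFF1 (-0.43) fell, and GREB1 (0.25), PGR (0.23), MYC (-0.29), NRIP1 (0.24), RARA (0.05), CCND1 (-0.09) and ESR1 (-0.02) did not pass the test.

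Under FULV 4469 regions rose and 652 fell. DESeq2 called 2995 and 76, library totals gave 3676 and 1899, unscaled counts 6470 and 74 and TMM near gene ends 2913 and 6621. The last 3 had median shifts of -0.13, 0.35 and -0.30. Without scaling the calls at TFF1, at the XBP1 panel region and at MREG were lost. TFF1 was not called without either DMSO library (-0.40 and -0.41), either E2 library (-0.42 and -0.40) or FULV replicate 2 (-0.36), and XBP1 not without DMSO replicate 1 (-0.43). Without DMSO replicate 2 the calls came to 2711. The count that fell was 205 and 145 without DMSO replicates 1 and 2, 438 without E2 replicate 1, and 362 and 1191 without FULV replicates 1 and 2. The count that rose was 2566 without DMSO replicate 2. Without E2 replicate 2, 4246 of 4638 calls rose and the others fell. Near estrogen-induced genes 8 of 153 regions rose and 14 fell (8 and 15 adjusted over the list alone). Those that rose included CCND1 (chromosome 11, 69642779 to 69643458, 7.18 ± 3.68 to 49.1 ± 15.5 CPM, 2.78). An XBP1 region 0.373 kb from the nearer gene end rose as well (82.0 ± 3.74 to 182 ± 14.3 CPM, 1.15). Those that fell included a region inside GREB1 (-1.47) and one inside SGK3, a kinase gene (-1.26). The camera adjusted p was 0.267 with an estimated correlation and 0.0116 with the preset one. Without scaling 16 regions of the list rose and 4 fell, and with TMM near gene ends 7 rose and 55 fell. Immediate early genes had 17 that rose and 3 that fell of 69 (18 and 6 adjusted over the list alone), near 12 and 2 genes. The luminal list had 14 and 9 of 187, coregulators 12 and 7 of 149 (11 and 4 adjusted over the list alone), cell cycle genes 5 and 0 of 25, housekeeping genes 7 and 0 of 34, basal genes 1 and 0 of 19 (0 and 0 adjusted over the list alone) and other lineages 0 and 0 of 8 (edgeR QL), with no other camera call. With TMM near gene ends the luminal list had 10 that rose and 70 that fell, coregulators 6 and 46, immediate early genes 13 and 13 and housekeeping genes 6 and 5. The housekeeping list had a median of -0.00253, a mean of 0.13 and a test direction upward. The basal list (median 0.02, mean 0.04) and the other-lineage list (mean 0.04, median -0.03) had test directions downward.

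H3K27ac was lower with FULV than with E2 at regions picked for the smallest p in this contrast and at several panel regions. The log2 change was -2.41 at SHANK2 (SE 0.151, edgeR QL adjusted p = 9.71e-11), -2.94 near CYP2A7, -2.38 at TH, -2.29 near DICER1, -2.20 near MLPH, the melanophilin gene, and -2.25 at the GREB1 enhancer (chromosome 2, 11539115 to 11540694, 98.0 ± 3.25 to 20.5 ± 0.671 CPM), the place of the GREB1 ER region. The panel regions of GREB1 (-1.96), XBP1 (-1.28), PGR (-0.95), MYC (-0.95), NRIP1 (-0.86) and TFF1 (-0.84) were lower, while RARA (-0.16), CCND1 (0.02), GATA3 (-0.10) and ESR1 (0.35) did not pass the test. H3K27ac was higher with FULV near FBXW7 (0.76), 33.2 kb from APOBEC3A, a cytidine deaminase gene (1.06), and inside CDK6, a cell cycle kinase gene (38.3 ± 1.80 to 65.1 ± 1.02 CPM, 0.77).

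In this contrast 214 regions were higher under FULV and 1524 lower, and DESeq2 called 14 and 592. The count of higher regions was 41 unscaled, 16 and 36 without E2 replicates 1 and 2, 113 and 110 without DMSO replicates 1 and 2, and 565 and 634 without FULV replicates 1 and 2. Without E2 replicate 1 the calls came to 829, with FBXW7 (0.64) and CDK6 (0.72) not called, and without E2 replicate 2 to 866, with APOBEC3A (0.85) not called. Of 153 regions near estrogen-induced genes 68 were lower and 0 higher (98 and 0 adjusted over the list alone), near 23 genes, with a camera adjusted p of 0.00575 with an estimated correlation. The count was between 58 and 66 with 0 higher with library totals, unscaled counts and TMM near gene ends. Examples were IGFBP4 (-1.93) and CTSD (86.1 ± 8.62 to 28.8 ± 1.48 CPM, -1.58). Immediate early genes had 12 lower and 1 higher of 69 (17 and 2 adjusted over the list alone), with camera adjusted p = 0.389 with an estimated correlation and 0.00136 with the preset one. Luminal genes had 15 and 3 of 187 (19 and 4 adjusted over the list alone). Lower regions included one at KRT19, a keratin gene (-1.05), and one inside ESR1, 2.12 kb from its nearer end (-1.27). Coregulators had 2 and 0 of 149 (NCOR2 and NCOA3), cell cycle genes 1 and 0 of 25, housekeeping genes 0 and 0 of 34, basal genes 0 and 0 of 19 and other lineages 1 and 0 of 8 (3 and 0 adjusted over the list alone). The coregulator list had a median of -0.02 and a test direction upward.

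Of the rises with FULV, a larger share was found with E2 too for H3K27ac than for ER (70.1%), a difference not tested. Simulated 2-fold changes were recovered at 6% and 11% for ER with E2 and FULV, and at 55% and 53% for H3K27ac regions. In the consensus lists, 87.0% of E2 regions for ER and 84.1% for H3K27ac overlapped a FULV region. Of 4469 H3K27ac regions that rose with FULV, 3981 (89.1%) rose with E2 too, where independent lists would share 725. FOSL2, ING5, UBE2J1 and RAB2A were among them. Another 147 fell under both against 32.1. Of these 3981 regions 75.8% (exact 95% interval 74.4 to 77.1) lay within 1 kb of a gene end, against 29.3% of all tested regions. An ER region overlapped 51.2% of them, against 55.7% of all tested regions. Of the 1524 regions higher with E2 than with FULV, such as those at SHANK2 and TH, 11.8% lay near a gene end and 92.8% overlapped an ER region. The 214 regions higher with FULV than with E2 were alike in this, at 8.88% and 84.6%. The Pearson correlation of the E2 and FULV changes was 0.746 across 35420 regions, against 0.556 in 20 simulations of unchanged groups with the same DMSO libraries. These simulations hold no changes, so their lack of shared calls does not bear on the number shared here. The covariance was 0.312 against 0.0536, a difference of 0.258. With 1 DMSO library for each contrast the correlation was 0.565 and 0.541 and the covariance 0.216 and 0.209, and part of the excess may come from the shared controls.

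At ER sites, H3K27ac was counted in windows of about 1 kb on the centres of the 43939 ER regions, of which 29811 were tested. The windows with the highest counts of GREB1 (log2 change 2.31, 32.0 ± 5.30 to 158 ± 26.7 CPM), XBP1 (1.91), GATA3 (1.55), NRIP1 (1.16), PGR (1.05), RARA (0.66) and MYC (0.65) rose with E2 against DMSO, and those of TFF1 (0.34), CCND1 (-0.05) and ESR1 (-0.32) did not pass the test. With FULV against DMSO, XBP1 (1.46) and GATA3 (1.41) rose and the other 8 did not pass. With FULV against E2, GREB1 (-1.93), PGR (-1.12), MYC (-0.99), NRIP1 (-0.86), RARA (-0.78), TFF1 (-0.68) and XBP1 (-0.45) were lower. Over all windows 3607 rose and 995 fell with E2, 2339 and 308 with FULV, and 199 were higher and 1758 lower with FULV than with E2. With library totals the splits were 2849 and 2626, 1955 and 988, and 291 and 1613, without scaling 5734 and 45, 3406 and 30, and 42 and 1335, and with DESeq2 2249 and 126, 1956 and 45, and 20 and 504. Without DMSO replicate 2 the E2 calls came to 2511 and the FULV calls to 1553. Without E2 replicate 1 the E2 calls came to 2754. The FULV against E2 calls came to 1118 without E2 replicate 1 and 1143 without E2 replicate 2. Without DMSO 1, DMSO 2, E2 1, E2 2, FULV 1 and FULV 2 in turn, the windows that fell with E2 were 543, 204, 248, 460, 1494 and 1667. Those that fell with FULV were 158, 122, 274, 244, 159 and 848, and those higher with FULV than with E2 were 161, 161, 33, 62, 478 and 576.

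Sites that gained ER with E2 had a median gain of acetylation with E2. Of 8190 such sites 6076 were tested, 1842 rose in H3K27ac and 24 fell, and the median log2 change was 0.42 (fry adjusted p = 0.00187, over 27 set tests). That median was 0.254 with library totals, 0.783 with unscaled counts and 0.118 at the 24082 sites gained in the unscaled ER fit. At the 4702 sites that gained ER with FULV, 4102 of them tested, H3K27ac rose with FULV at 562 and fell at 42, with a median of -0.10 and a mean of 0.04. The fry test at these sites had an upward direction, opposite in sign to the median, and passed 0.05 alone but not after adjustment over the 27 set tests (fry adjusted p = 0.0505). The unadjusted call was lost without DMSO replicate 2 (median -0.06) and without E2 replicate 1 (-0.10), and with library totals the direction was downward (median -0.24). The same sites had a median of 0.28 with E2 against DMSO, with 1162 that rose and 86 that fell. At the 3295 sites that gained ER under both treatments, 2939 of them tested, the median H3K27ac change was 0.43 with E2 and -0.10 with FULV. With FULV 436 of these sites rose and 40 fell, with a mean of 0.05 and an upward fry direction (adjusted p = 0.0627). The difference between treatments was -0.40 (fry adjusted p = 0.00187), with 734 sites lower and 3 higher under FULV. This difference was -0.145 at the 23604 sites gained under both in the unscaled ER fit. The median library level at these sites was 3.94 ± 0.0258 log2 CPM in DMSO, 4.49 ± 0.0171 in E2 and 3.98 ± 0.0686 in FULV. At the 1407 sites called gained with FULV and not with E2, 1163 of them tested, 126 (10.8%) rose and 2 fell in H3K27ac with FULV, with a median of -0.106. These values lay near those of other sites. Of 12243 tested sites without an ER call in any contrast 9.11% rose with FULV, with a median of -0.115. Over all tested sites the median was -0.133. Of the tested sites that gained ER with FULV 13.7% rose. At the 6724 sites with more ER under FULV than under E2, 116 of 5123 were higher and 14 lower in H3K27ac under FULV (median 0.15), which fry did not call.

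**Figure D3:**
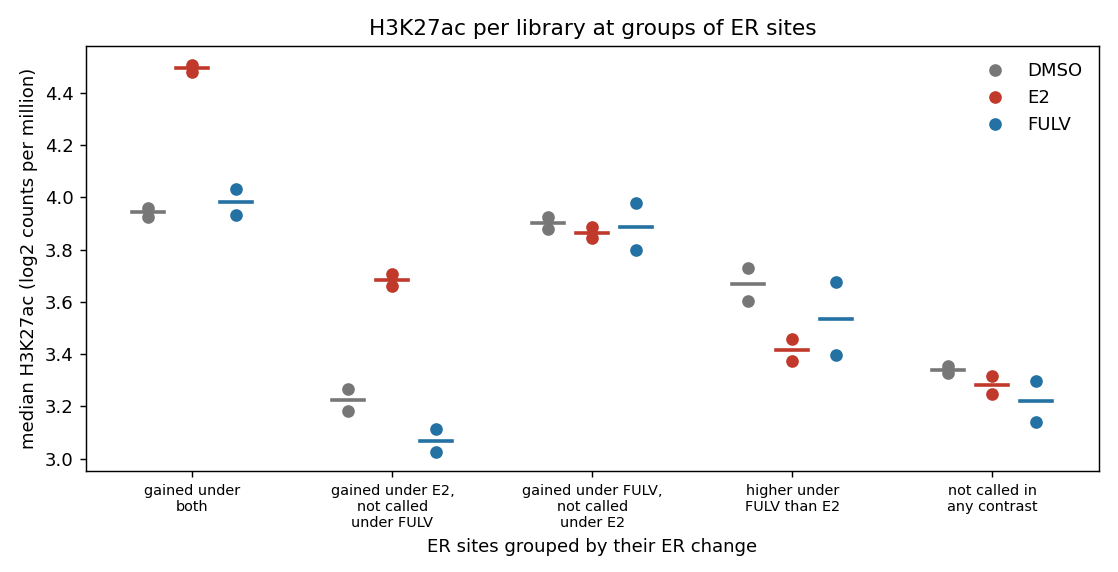
Median H3K27ac (log2 CPM, vertical axis) over the sites of 5 groups chosen from the ER libraries, with a point per H3K27ac library and treatments by colour. At sites that gained ER under both treatments the mean of the library medians is 4.49 in E2, 3.94 in DMSO and 3.98 in FULV.

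Across the 28868 sites tested in both assays, which are not independent replicates, the change in H3K27ac followed that in ER with E2 (Spearman 0.475, Pearson 0.507) and less so with FULV (Spearman 0.0958, Pearson 0.200). The difference between these correlations was not tested. The change between FULV and E2 had a Spearman correlation of 0.509 and a Pearson correlation of 0.569, the last of 3 relations computed. With the sites cut into 10 equal groups by ER change under E2, the group with the highest change (ER median 2.77) had a median H3K27ac change of 0.67 and the group with the lowest (ER median -1.91) one of -0.29. For FULV the highest group had an ER median of 1.91 and an H3K27ac median of -0.02, and the lowest -1.49 and -0.16.

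**Figure D4:**
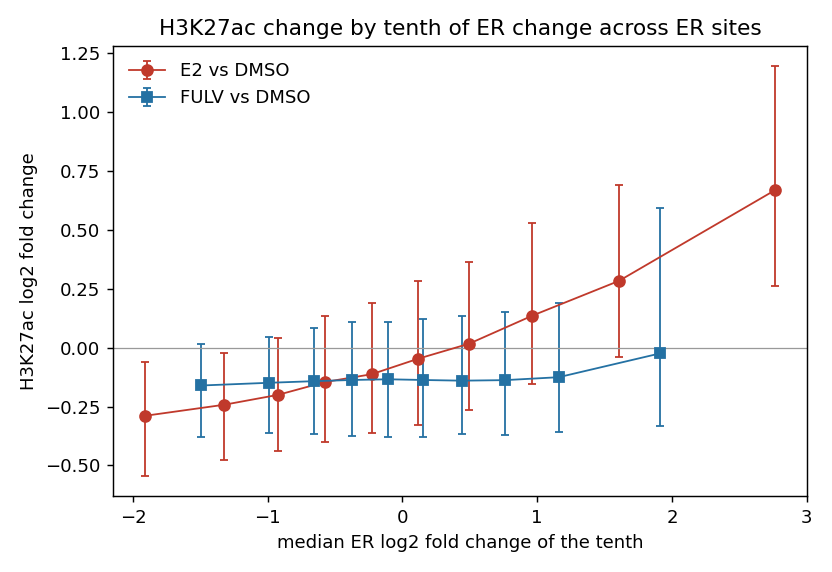
Median H3K27ac log2 change (vertical axis, bars from the lower to the upper quartile) against median ER log2 change (horizontal axis) in 10 equal groups of the 28868 sites ordered by ER change, for E2 against DMSO and FULV against DMSO. The highest group lies at an ER change of 2.77 and an H3K27ac change of 0.67 for E2, and at 1.91 and -0.02 for FULV.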

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

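The alternatives TMM near gene ends and TMM on the regions in all 3 ER lists were chosen after the results were seen, and the others were set beforehand. TMM set near transcription start sites and the motif alternatives were not run, since they need positions not used here. Where no cause is named, the cause was not tested. DESeq2 lowered the calls to 5166 (ER, FULV against DMSO), 8971 (ER, FULV against E2), 3793, 3071 and 606 (H3K27ac regions, E2, FULV and FULV against E2), and 2375 and 524 (H3K27ac at ER sites, E2 and FULV against E2). Unscaled counts, which by construction count a higher total as a rise, gave 24148, 38132 and 24847 ER calls in the 3 contrasts, and TMM near gene ends 11800 and 9534 H3K27ac calls for E2 and FULV. Library totals kept each count within 1.5 times but turned the split of ER calls, and no count filter left all 9 counts within that range. Of the 5166 DESeq2 calls 5160 were also calls of the TMM fit, and of the 3793 all 3793.

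Leaving out 1 library, where the lone replicate is assumed to vary like the other groups, gave 6760 to 12889 ER calls for E2, 3070 to 8082 for FULV and 10002 to 17811 for FULV against E2. For H3K27ac regions the ranges were 3802 to 9363, 2711 to 6706 and 829 to 2270, and at ER sites 2511 to 5996, 1553 to 3926 and 1118 to 2246. The fry test at sites with ER gained under E2, and that of FULV against E2 at sites gained under both, kept direction and an unadjusted p below 0.05 with library totals, unscaled counts, TMM on the ER sites, sites from the unscaled ER fit and each library left out. They were not run with DESeq2 or without the count filter. The medians went from 0.118 (sites from the unscaled ER fit) to 0.783 (unscaled) for E2, and from -0.417 (unscaled, and without DMSO replicate 2) to -0.145 (sites from the unscaled ER fit) for FULV against E2. At sites gained under FULV the median was -0.236 with library totals (direction downward), 0.248 unscaled (upward, not called), -0.130 for sites from the unscaled ER fit (downward, 38122 sites) and -0.102 to -0.0198 with 1 library left out. The Spearman relation of ER and H3K27ac at sites with ER counts above the median was 0.521 for E2 and 0.0441 for FULV. With 1 library left out it was 0.418 to 0.457 and 0.0428 to 0.124. Those H3K27ac fits hold fewer libraries, although the library left out is not always of the groups compared. Split controls gave the E2 and FULV relation as 0.359 and 0.287 for ER and 0.565 and 0.541 for H3K27ac. Of E2 regions in the FULV list, 86.2% (ER) and 81.6% (H3K27ac) shared at least 50% of their length and 86.3% and 91.1% did so by 1 bp among higher-score regions. ER regions inside H3K27ac regions under FULV were 40.7% and 56.2%. In the ER contrast of E2 with DMSO 6% of simulated 2-fold changes were recovered. Depth was not varied, so its part and that of replicate spread were not separated.

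The replicate numbers were checked for pairing: same-numbered libraries of 2 treatments had correlated deviations of 0.00352 to 0.0926 (ER) and 0.0518 to 0.152 (H3K27ac). With 2 libraries per treatment such values cannot decide whether same-numbered libraries were paired. With the replicate block the calls were 13109, 8356 and 18053 for ER, and 5872, 3488 and 2870 for H3K27ac at ER sites. For H3K27ac regions they were 9356 (2788 fell), 6438 (1297 fell) and 2801 (655 higher and 2146 lower with FULV than with E2). Each count lay above that without the block. The fry tests run with it were those at sites gained under E2, under FULV, and under both for FULV against E2. Their unadjusted calls did not change.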

Other observations

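The test at sites matched on ER was set before its result was seen, and separate DMSO libraries and TMM on the ER sites were settings chosen before the data were examined, while their use against the patterns below and the other tests were chosen after the results were seen. At some AP-1 and other immediate early genes, which encode transcription factors switched on within minutes of many stimuli, H3K27ac rose with both ligands. Of the 69 regions of that list 23 rose and 1 fell with E2 and 17 rose and 3 fell with FULV, with no camera call at an estimated correlation (adjusted p = 0.330 and 0.459), and with TMM near gene ends the counts were 16 and 8, and 13 and 13. Next to JUNB (chromosome 19, 12793446 to 12794222) it was 24.2 ± 6.69 CPM in DMSO, 94.4 ± 10.3 in E2 and 88.4 ± 8.89 in FULV, log2 changes of 1.98 and 1.88 (edgeR QL adjusted p = 1.07e-08 and 4.21e-08). KLF6 (1.43 and 1.42), EGR1 (0.90 and 0.88) and KLF4 (1.31 and 0.87) did likewise, and each of these directions held with library totals, unscaled counts and TMM near gene ends. Among 34 housekeeping regions 7 rose and 1 fell with E2 and 7 rose and 0 fell with FULV (edgeR QL), camera did not call the list (adjusted p = 0.550 and 0.459), and with TMM near gene ends the counts were 5 and 6, and 6 and 5. Single regions near ACTB (107 ± 15.3 to 244 ± 24.1 and 250 ± 87.3 CPM, 1.20 and 1.23), PPIA (1.31 and 1.12), YWHAZ (570 ± 67.9 and 582 ± 158 CPM from 283 ± 18.1, 1.37 kb from a gene end) and the replication gene MCM4, of the cell cycle list (0.97 and 0.78), kept both calls under those 3 scalings.

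At some distal regions acetylation went opposite ways. The region 15.0 kb from FOSL2 (chromosome 2, 28376928 to 28378780) rose from 123 ± 13.1 to 203 ± 3.08 CPM with E2 (0.73). It fell to 76.4 ± 7.71 with FULV (-0.68, edgeR QL adjusted p = 0.000591), while the region at an end of the same gene rose under both. ESR1 had such a region inside the gene (chromosome 6, 151657965 to 151659625, 0.74 and -0.54), and GATA3 one 53.4 kb away (chromosome 10, 8128108 to 8129125, 0.77 and -1.18), while regions inside that gene rose under both (1.84 and 1.57 at chromosome 10, 8049515 to 8050410). In all 93 H3K27ac regions were called in opposite directions.

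The first pattern weighed is the rise of H3K27ac under both treatments at 3981 regions (medians of 1.08 and 1.04), 3018 of them within 1 kb of a gene end. Chance values of the shared DMSO libraries are argued against, since with a separate DMSO library for each contrast the correlation of the changes was still 0.541. A uniform shift of all regions near gene ends is argued against as the whole cause, since with TMM set on those regions 64.4% of the 3981 and 1931 of the 3018 still rose under both, although the 10393 near-end regions had medians of 0.27 and 0.26 (lower quartile -0.0950 with E2). The share of H3K27ac counts near gene ends was 42.2 and 41.1% in the DMSO libraries and 46.6 to 50.0% in the treated ones, a gap of 4.35 points, so a difference in library preparation that hits some regions more than others cannot be told apart from treatment without a labelled batch. A response to handling, vehicle or either ligand stays open and was not tested.

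The next pattern is the lower H3K27ac with FULV than with E2 at sites that gained ER under both. Less ER under FULV may account for part of it, because across these sites the changes of ER and H3K27ac between FULV and E2 correlate (Pearson 0.611 across sites, which are not replicates). With the main scaling less ER is argued against as the whole cause. At 721 tested sites where ER differed by less than 0.25 the median was still -0.158 (quartiles -0.451 and 0.0248, called by fry without adjustment). A bound of -0.1 had been set beforehand, and at 198 sites with ER called higher under FULV the median was -0.119. The match is loose and the value near its bound. Sites matched in replicate 1 had ER at -0.154 in the other replicate and H3K27ac at -0.174 (0.0957 and -0.158 when matched in replicate 2). TMM on the ER sites gave -0.0989, which lies inside the bound, so with that scaling less ER is not argued against. ER scaled by library totals gave -0.400, and over all tested ER sites the median was -0.0459. The size of the remainder stays open. Scaling of the H3K27ac libraries is argued against as the cause of the whole pattern, whose median was -0.336 with TMM on the ER sites (called by fry), and a candidate explanation left open is that ER bound with the antagonist is followed by less acetylation.

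The last pattern is the ER regions called lower than in DMSO, such as those near PLEC, SCRIB and RSL24D1. Of those called lower under FULV, 2.77% held fewer unscaled counts than in DMSO (34.6% under E2), so a scaling effect of libraries with unlike ER enrichment cannot be told apart from loss of ER without the total of mapped reads. A larger share of background cutting at gene ends in the DMSO libraries would go with the location of these regions, but so would a loss of ER there. Whether these ends are open was not measured. Of those called lower under FULV 31.3% (exact 95% interval 29.7 to 33.0) lay within 1 kb of a gene end. Under E2 the share was lower, at 22.4% (21.1 to 23.6), against 14.9% of all tested regions. The share of ER counts near gene ends was 21 and 20.6% in DMSO, 15.3 and 14.3% in E2 and 19.2 and 16.5% in FULV. These shares come from the same counts as the calls, so the location does not separate background from loss of ER. They were lowest in E2, whose regions called lower lay near gene ends less often than those of FULV. Counts of the IgG libraries, which could separate background from ER, were not used here.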
